A study of Mus musculus with 6 samples.

How the data were processed

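The measurements are poly(A) RNA-seq values of 6 libraries of E12.5 mouse telencephalon, 3 labelled wild-type and 3 labelled Arl13b mutant, grouped by the genotype in the labels. The authors deposited 1 table of variance-stabilised normalized counts, which are values on a log2 scale, for 24444 gene symbols. Per the submitters' processing notes, CASAVA, STAR 2.6.0, Salmon 0.9.1, DESeq 1.16.1, DESeq2 and the mouse build mm9 were used, with no role or order given. The annotation and any filter are not given in the sources used here. RNA was extracted with a column kit, per the labels' protocols. Deposited values ran from 5.13 to 18.39, and the lowest value was shared by all libraries. No coordinates are given because the reference at hand is of another build. Of the symbols, 23793 (97.3%) were found in the reference gene table. No mitochondrially encoded gene was among the symbols, so that marker list was not tested.

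The shared lowest value is the transformed value of a count of 0, which fixes the constant of the parametric transformation, and the transformation was inverted to give normalized counts. Within each library, the lowest inverted values lay at 1 and 2 times a common step and none at 1.5 times, and this step, between 0.537 and 1.31, was taken as the value of 1 read. Between 54.8% and 72.6% of values under 30 reads were within 0.05 of a whole number of reads, so no count test was run. Depth estimated from the step was between 27700000 and 51500000 reads, and precision at low counts is limited by it.

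Genes were kept if their mean was at least 1 above the lowest value in the table, which left 14249. The groups were compared with limma 3.58.1 in R 4.3.3, with moderated tests, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, two-sided. A difference is a difference of mean variance-stabilised values, which understates the change of low genes. Of 30 gene lists with 762 genes, 745 genes were in the table, and 29 lists had at least 5 measured genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists, the tests, the rule for named genes and the other settings listed last, except those said to be added, were fixed before the data were examined. The rule names Arl13b, up to 12 genes per direction with the largest change among those past the threshold with non-overlapping groups or, where there are none, the 5 with the smallest p per direction, up to 4 members of each list discussed with the smallest p, and 17 genes fixed in advance. Predicted genes, pseudogenes and sex-linked genes are skipped and the next gene is taken.

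After the values were seen, the same tests were repeated on wild-type 2 and 3 against Arl13b-null 1 and 3, because the other 2 libraries stood apart, and the rule for named genes was applied to that fit as well. Genes named for single libraries (Tbr1, Mki67, Stmn2 and others) and 4 marker lists for cornified epidermis, maturing neurons, embryonic globins and adult globins were also chosen then. With 2 libraries per group, exact permutation cannot reach 0.05, and only the limma test is given. Figures were drawn with matplotlib 3.10.9.

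The tests were tested on simulated data with the real means and residual spread, independent noise between genes and 200 changed genes. With 6 libraries, 2% of genes changed by 1, 32% of those changed by 2 and 64% of those changed by 4 log2 units were recovered. With 4 libraries, 80%, 94% and 92% were recovered. Of genes changed by 0.5, 0% were recovered with 6 libraries and 28% with 4. Unchanged genes called numbered 7 with 6 libraries and 3 with 4. The spread of the 4 libraries was taken from libraries kept because the other 2 stood apart, so recovery with 4 may be overstated. Alternatives were no filter and a stricter filter, centring, quantile normalization, no trend, robust moderation, library weights, a replicate block, inverted counts and leaving out each library. Library weights estimated gene by gene and all settings of the comparison of 4 libraries were added after the values were seen.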

Results

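Poly(A) RNA was sequenced from the telencephalon, the forebrain region that forms the cerebral cortex and basal ganglia, of mouse E12.5 embryos of the C57BL/6J strain. The series holds 3 libraries labelled wild-type and 3 labelled as homozygous mutants of Arl13b, here called Arl13b-null 1 to 3. Arl13b encodes a small GTPase of the primary cilium, and the series concerns cilia and the development of axon tracts. The deposited table gives variance-stabilised values, on a log2-like scale, for 24444 gene symbols. Undoing the transformation gave normalized counts that summed to 27700000, 27500000 and 27900000 in wild-type 1 to 3, and to 28300000, 36200000 and 29200000 in Arl13b-null 1 to 3. From the size of a single read, the depth was estimated as 51500000, 41400000 and 35300000 reads in wild-type 1 to 3 and 38600000, 27700000 and 47100000 in Arl13b-null 1 to 3. The labels do not say whether the libraries came from separate embryos, so the p-values measure only the spread between these libraries, which may be technical in part.

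Wild-type 1 and Arl13b-null 2 did not resemble the other 4 libraries in their cell-type markers. Relative to the mean of wild-type 2 and 3, the mean of 36 cell cycle genes differed by −4.52 on the log2 scale in Arl13b-null 2 and by −1.97 in wild-type 1, but by 0.053 and 0.13 in Arl13b-null 1 and 3. Mki67, a marker of dividing cells, had 3596 normalized counts in wild-type 1 and 102 in Arl13b-null 2, against 13025 in Arl13b-null 1. Stmn2, a microtubule regulator of growing neurons, had 33432 in wild-type 1 and 124879 in Arl13b-null 2, against 14020 in Arl13b-null 1. Radial glial genes differed by −0.74 in wild-type 1 and −3.53 in Arl13b-null 2, and postmitotic neuron genes by 0.79 and 1.05. Hbb-y, an embryonic globin, was listed at 0 in Arl13b-null 2 and had 397 normalized counts in wild-type 1, against 61914 in Arl13b-null 1 and 160378 in Arl13b-null 3.

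**Figure D1:**
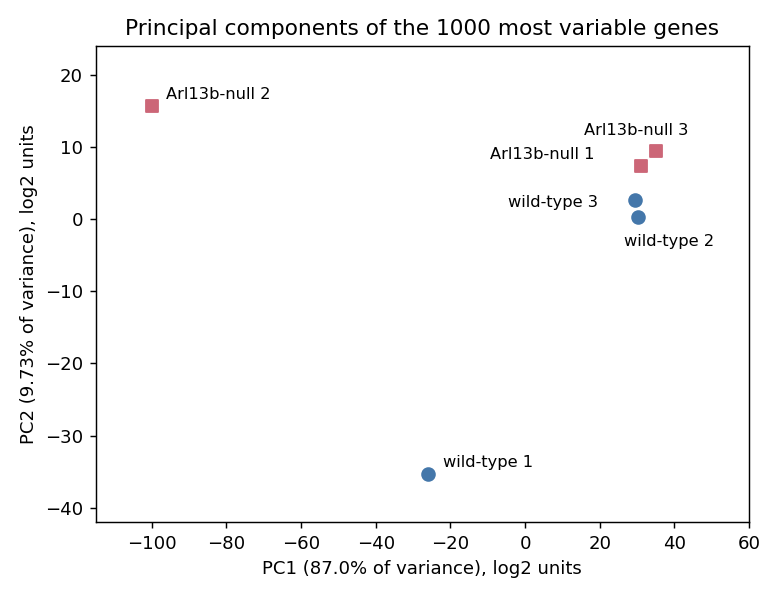
Scores of the 6 libraries on the first 2 principal components of the 1000 most variable genes, in log2 units, with circles for wild-type and squares for the libraries labelled Arl13b-null. Arl13b-null 2 lies at −100.03 and wild-type 1 at −25.93 on the first component, and the other 4 libraries lie between 29.41 and 35.16.

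The first principal component held 87.0% of the variance of the 1000 most variable genes and set these 2 libraries apart from the rest. Across genes, which are not independent replicates, the Pearson correlation among the other 4 libraries was between 0.985 and 0.995, whereas Arl13b-null 2 correlated with them at between 0.702 and 0.722. Wild-type 1 correlated with them at between 0.880 and 0.898. No pair of libraries agreed within sampling noise, as the lowest chi-square per degree of freedom was 10.5. Wild-type 2 and 3 and Arl13b-null 1 and 3 are called the 4 coherent libraries below, a choice made after the values were seen.

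**Figure D2:**
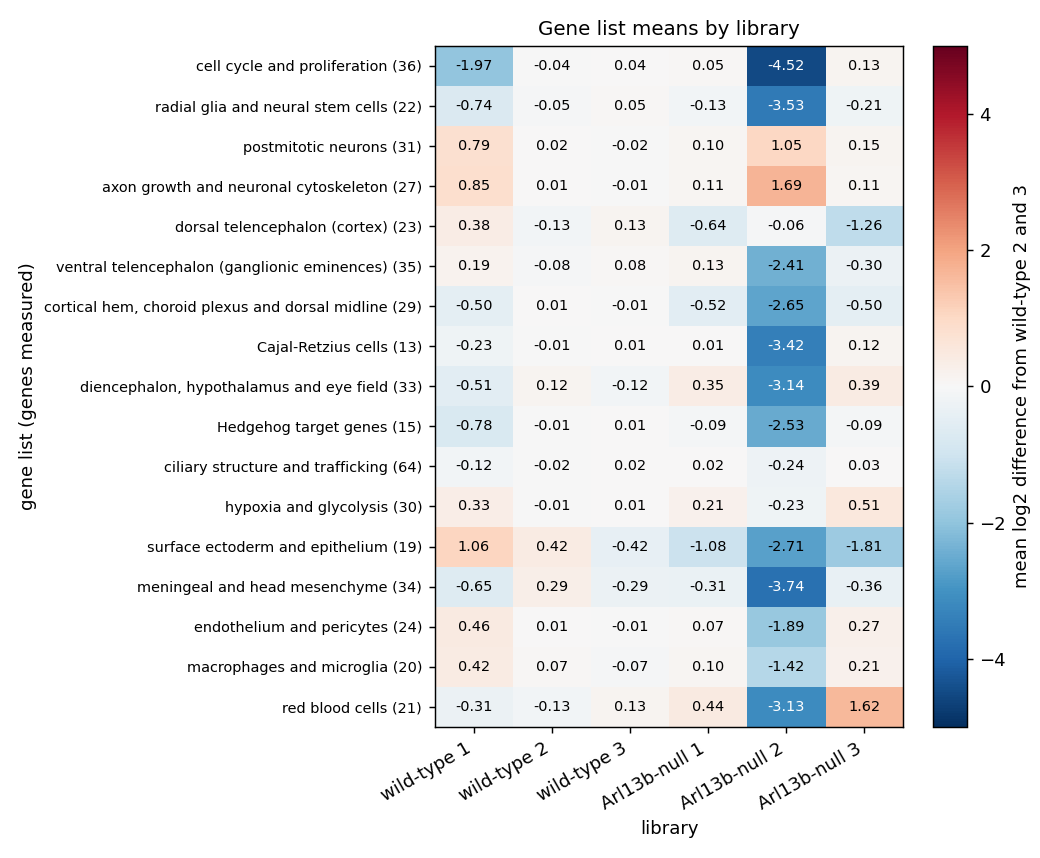
Mean log2 difference of each gene list (rows, with the number of genes measured) from the mean of wild-type 2 and 3, in each of the 6 libraries (columns). The cell cycle list stands at −1.97 in wild-type 1 and −4.52 in Arl13b-null 2, and between −0.039 and 0.13 in the other 4 libraries.

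Arl13b itself was expressed at similar levels in both groups. It had 661, 553 and 560 normalized counts in wild-type 1 to 3 and 492, 532 and 564 in Arl13b-null 1 to 3. The variance-stabilised level was 9.36 ± 0.13 (SD, n = 3) in wild-type and 9.22 ± 0.088 (SD, n = 3) in the libraries labelled Arl13b-null. The difference of −0.14 ± 0.20 (SE) was within the spread of the replicates (limma, adjusted p = 0.990; exact two-sided permutation p = 0.3, where 0.1 is the smallest p that 3 against 3 can give). A gene-level value does not show which part of the transcript was sequenced, so the transcript does not check the genotype labels, and every direction below rests on the libraries as labelled.

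The comparison of all 6 libraries asks which transcripts differ in the telencephalon without Arl13b. With predicted genes skipped, the genes with the smallest p were lower in the libraries labelled Arl13b-null: Dct, an enzyme of melanin synthesis (−1.96 ± 0.28, SE, on the log2 scale), Fermt1, an integrin-binding protein of epithelia (−1.25 ± 0.19), Trp73, a transcription factor of Cajal-Retzius cells (−2.28 ± 0.38), Spint1, an epithelial protease inhibitor (−1.71 ± 0.30), and the ligand gene Wnt10b (−1.43 ± 0.25). Among higher values the smallest p belonged to Ciart, a circadian repressor (0.99 ± 0.25), Ctgf (1.04 ± 0.27), the glycolytic enzyme gene Aldoa (0.73 ± 0.20), Slc30a3 (0.76 ± 0.23) and Bnip3 (0.98 ± 0.31). All 10 had non-overlapping groups of 3, but none passed, with an adjusted p of 0.990 for each in limma. Of 14249 genes tested, 0 passed an adjusted p of 0.05 in limma, and 163 had an unadjusted p under 0.05, of which 16 were higher and 147 lower, where 712 are expected by chance. The groups did not overlap for 1177 genes, or 8.26%, against 10% by chance. Leaving out wild-type 1 gave 4 genes, all Y-linked, and the 4 coherent libraries gave 36.

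Lists of epithelium, mesenchyme, the cortical hem and the dorsal and ventral telencephalon were lower in the libraries labelled Arl13b-null over all 6 libraries. The surface ectoderm and epithelium list had the largest mean difference, −2.22 over 19 genes (camera with a preset correlation, adjusted p = 4.61e-29, and 0.338 with an estimated correlation), and included Cldn4 (−2.43 ± 0.48, SE), Krt8 (−2.68 ± 0.60), Trp63 (−2.08 ± 0.47) and Sfn (−2.76 ± 0.66). Wild-type 1 carried skin transcripts: this list lay 1.06 above the mean of wild-type 2 and 3 there, and Krt5, a basal keratin, had 5392 normalized counts, against 917 and 487 in wild-type 2 and 3. The meningeal and head mesenchyme list, with the collagen gene Col1a1 (−2.97 ± 1.80), Postn (−2.22 ± 0.87) and Dcn (−1.14 ± 0.46), had a mean of −1.26 (adjusted p = 5.36e-11, and 0.549 with an estimated correlation). The list of cortical hem, choroid plexus and dorsal midline, with Wnt2b (−1.02 ± 0.27), Ttr (−4.75 ± 1.39) and Clic6 (−2.29 ± 0.68), had a mean of −1.06 (adjusted p = 1.19e-09, and 0.549 with an estimated correlation). The ventral telencephalon list, with Lhx6 (−1.64 ± 0.70) and Lhx8 (−1.82 ± 0.77), had a mean of −0.92 (adjusted p = 8.15e-10, and 0.549 with an estimated correlation), and the dorsal list, with Eomes (−3.31 ± 0.85), had a mean of −0.78 (adjusted p = 0.00252, and 0.338 with an estimated correlation). In all, 20 of 29 lists passed with the preset correlation, 18 lower and 2 higher, against 0 with an estimated correlation, 0 with fry and 0 with its mixed test. Splits of the 6 libraries that mix the labels, made after the results were seen, gave 12 to 21 lists with the preset correlation. The small p-values of that test therefore do not bear on genotype by themselves. Exact two-sided permutation of the library means gave p = 0.1 for the ectoderm and hem lists, 0.2 for the dorsal, 0.3 for the ventral and 0.4 for the mesenchyme list. Adjusted over the list alone, the smallest p was 0.0338 for the hem list, 0.0152 for Cajal-Retzius cells, 0.0139 for the diencephalon list and 0.0260 for surface ectoderm. Leaving out Arl13b-null 3 ended the dorsal call (mean −0.48, adjusted p = 0.169), and took Lhx6 to −0.96. Leaving out Arl13b-null 1 took the ventral mean to −1.41. Leaving out Arl13b-null 2 took Col1a1 to −0.92 and the hem mean to −0.35 (adjusted p = 0.0127, and 0.746 with an estimated correlation), ended the mesenchyme and ventral calls (means −0.12 and −0.15, adjusted p = 0.221 and 0.495), left 9 lists past the threshold and turned the sign of the cell cycle list from −0.79 to 0.75 and of the red blood cell list from −0.25 to 1.13.

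Among the 4 coherent libraries, 2 Hedgehog co-receptor genes were lower and Fgf15, Gbx2 and Six3 higher in those labelled Arl13b-null. Gas1 and Cdon, which encode co-receptors of Sonic hedgehog, fell by 1.18 and 1.29 on the log2 scale (SE 0.065 and 0.086, n = 2 per group), to 0.434 and 0.403 times the wild-type count. Gas1 had a mean of 5961 normalized counts in wild-type 2 and 3, 2528 in Arl13b-null 1 and 2642 in Arl13b-null 3. Of the libraries left out, wild-type 1 had 1585 for Gas1, below both of these Arl13b-null values, and Arl13b-null 2 had 456. Cdon had 2120 in wild-type 1 and 302 in Arl13b-null 2. Over all 6 libraries neither gene passed (limma adjusted p = 0.990 for each). Fgf15, a fibroblast growth factor of the forebrain, rose by 1.13 ± 0.051 (SE), to 2.26 times the wild-type count. It had 247 normalized counts in wild-type 1 and 6.56 in Arl13b-null 2, and over all 6 libraries it did not pass (limma adjusted p = 0.998). Gbx2, a transcription factor of the ventral telencephalon and thalamus, rose by 0.96 ± 0.093 and Six3, a forebrain transcription factor, by 0.66 ± 0.068. The limma adjusted p was 0.00734 for Gas1, 0.0156 for Cdon, 0.00412 for Fgf15, 0.0437 for Gbx2 and 0.0478 for Six3. Without the mean-variance trend Fgf15 kept its call (adjusted p = 0.0267), and the other 4 lost theirs, Gas1 barely, with an adjusted p of 0.0627 for Cdon, 0.0873 for Gbx2 and 0.102 for Six3. Without wild-type 2 the 5 calls ended (adjusted p between 0.0577 for Gas1 and 0.231 for Six3), and without wild-type 3 Gas1 and Fgf15 kept theirs (adjusted p = 0.0484 for each). Centring and inverted counts also ended the Six3 call (adjusted p = 0.0543 and 0.0544).

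In limma, 36 of 14249 genes passed in the 4 coherent libraries, 10 higher and 26 lower, of which 6 were genes of the fixed sex-linked list and 27 differed by at least 1. An unadjusted p under 0.05 was found for 2053 genes, against 712 expected, and the groups did not overlap for 47.5% of genes, against 33.3% by chance for 2 against 2. The groups also differed in sex-linked transcripts. Ddx3y, on the Y chromosome, had a mean of 1176 normalized counts in wild-type 2 and 3, 0 in Arl13b-null 1 and 1.23 in Arl13b-null 3, and Xist, expressed from an inactive X, had 120, 16292 and 19017. Sex and genotype therefore coincide in these 4 libraries, and no fit can separate them. Of the 36, leaving out wild-type 2, wild-type 3, Arl13b-null 1 or Arl13b-null 3 kept 6 (all of the sex-linked list), 9, 36 or 35, among 6, 17, 725 or 78 genes past the threshold. Without the trend 7 of the 36 kept their call, Fgf15, Etl4 and 5 genes of the sex-linked list, and with robust moderation 32 did. Each fit that leaves out 1 of these 4 libraries, for genes and lists, sets 1 library against 2 and takes its spread from the group of 2. A lost call there can come from the lost library's data or from the smaller number.

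**Figure D3:**
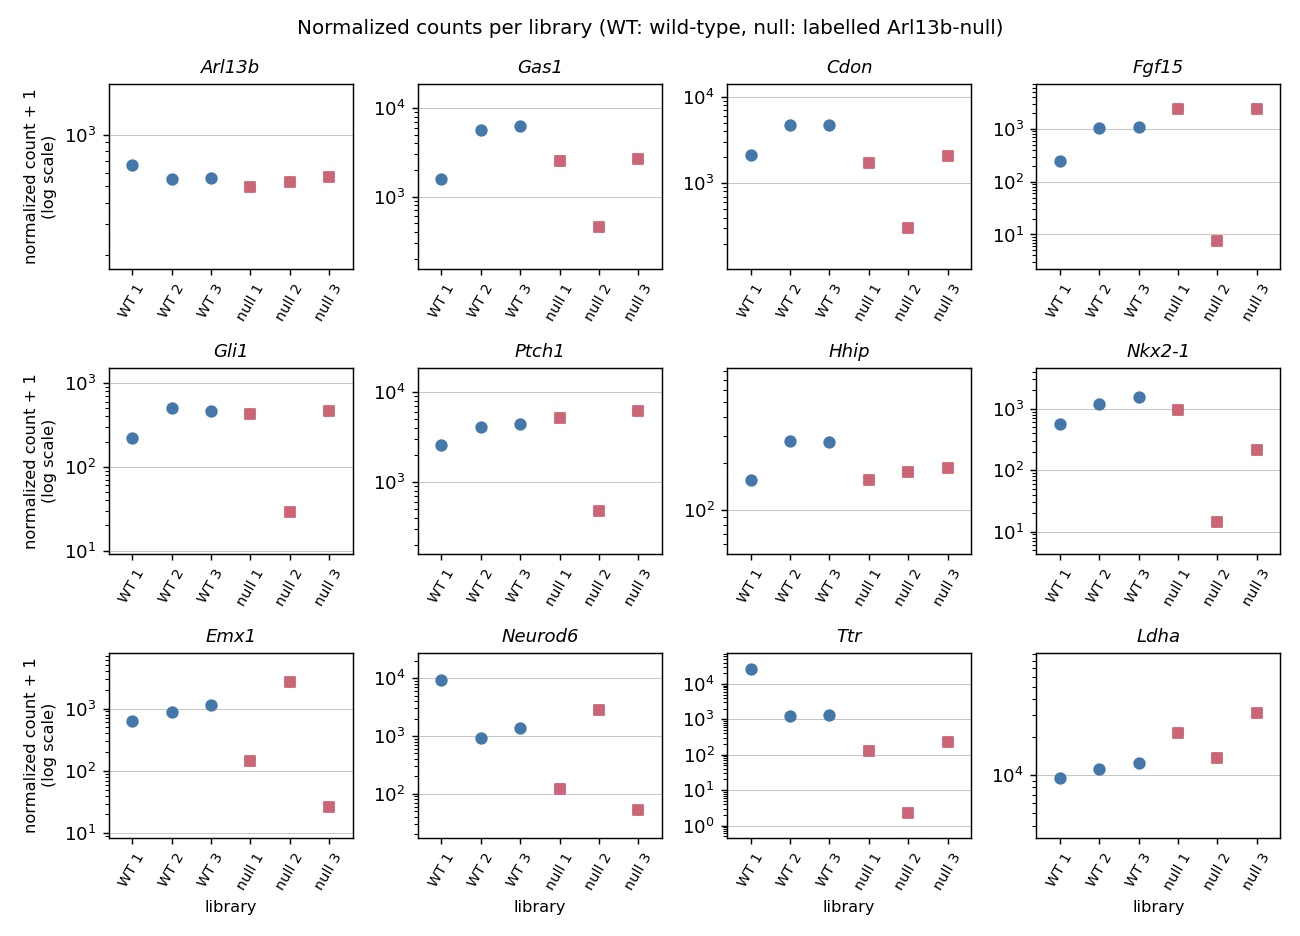
Normalized count plus 1 on a log axis for 12 genes in each of the 6 libraries, with circles for wild-type and squares for the libraries labelled Arl13b-null, 1 point per library. Gas1 and Cdon are lower and Fgf15 higher in Arl13b-null 1 and 3 than in wild-type 2 and 3, Emx1 has 25.0 normalized counts in Arl13b-null 3, and Arl13b lies between 492 and 661 in all 6.

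Hedgehog target genes did not move in 1 direction in the 4 coherent libraries. Ptch1, the Hedgehog receptor, differed by 0.39 ± 0.091 (SE) and Ccnd1 by 0.35 ± 0.067, while Hhip, a Hedgehog-binding inhibitor, differed by −0.54 ± 0.099 and Gli1, a transcriptional readout of the pathway, by −0.12 ± 0.081. None passed over all genes (limma adjusted p between 0.122 for Hhip and 0.557 for Gli1). Over the 15 genes of the list, 7 were above and 8 below 0, and 4 higher and 3 lower members passed adjusted over the list alone. The list mean was −0.088 (camera adjusted p = 0.629, and 0.829 with an estimated correlation), and fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.000412, and 12 of 29 lists passed that test. Of 21 pathway components, Gas1 and Cdon passed, and Shh (0.23 ± 0.15), Smo (−0.024 ± 0.044), Gli2 (0.16 ± 0.062) and Gli3 (−0.17 ± 0.081) did not.

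Genes of the cortex and of the cortical hem and choroid plexus were lower in the 4-library comparison. Neurod6 and Neurod2, transcription factors of excitatory neurons, fell by 3.08 ± 0.28 (SE) and 2.26 ± 0.20 (limma adjusted p = 0.0354 and 0.0348). Ttr, the thyroid hormone carrier made by the choroid plexus, fell by 2.50 ± 0.20 (adjusted p = 0.0323), Clic6 by 1.27 ± 0.12 (adjusted p = 0.0354) and Wnt2b, a signal of the hem, by 1.09 ± 0.092 (adjusted p = 0.0323). Of 29 hem genes, 17 were lower and 3 higher when adjusted over the list alone, and 3 lower over all genes. The mean was −0.51 (camera adjusted p = 2.21e-08, and 0.537 with an estimated correlation), and fry gave an adjusted p of 0.0499. Of 23 cortical genes, 13 were lower and 3 higher adjusted over the list alone, and 2 lower over all genes, with a mean of −0.95 and a median of −0.31 (camera adjusted p = 3.75e-06, and 0.619 with an estimated correlation). Emx1 (−3.06 ± 0.44), Emx2 (−1.21 ± 0.17), Slc17a7 (−1.55 ± 0.21), Tbr1 (−2.17 ± 0.61) and Eomes (−2.43 ± 0.60), which mark the cortical field and its neurons, did not pass over all genes. Without Arl13b-null 3, Tbr1 differed by −1.20 and Eomes by −1.48, and Emx1, Slc17a7 and Eomes passed (adjusted p = 0.00695, 0.0490 and 0.0328). Without Arl13b-null 1 all 5 passed, with the largest adjusted p, 0.00546, for Emx2. Robust moderation ended the calls of Neurod6, Neurod2 and Ttr (adjusted p = 0.105, 0.0671 and 0.0652). Inverted counts also ended the Neurod6 call (limma adjusted p = 0.0595). Pax6 differed by 0.12 ± 0.14, and this sign changed with the library left out.

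Among the 4 coherent libraries, Emx1, Nkx2-1 and Lhx6, transcription factors of the cortex and the ventral telencephalon, were lowest in Arl13b-null 3. Emx1 had 25.0 normalized counts in Arl13b-null 3 and 145 in Arl13b-null 1, against 1018 in wild-type 2 and 3. In the ventral telencephalon, Nkx2-1 had 211 in Arl13b-null 3 and 935 in Arl13b-null 1, against 1354, and Lhx6 had 94.0 and 804 against 914. The ventral list as a whole had a mean of −0.083 and a median of 0.088 (camera adjusted p = 0.513, and 0.829 with an estimated correlation), with 5 members higher and 2 lower adjusted over the list alone. Without Arl13b-null 3 its mean was 0.13 and camera called it higher (adjusted p = 0.0155, and 0.723 with an estimated correlation).

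Genes of the diencephalon, the forebrain region next to the telencephalon, were higher in the 4-library comparison. Gbx2, which is also on the ventral telencephalon list, passed over all genes, and Dbx1 (0.86 ± 0.14, SE) and Foxb1 (1.02 ± 0.18) did not. Adjusted over the list alone, 12 of 30 members were higher and 1 lower, Dct (−1.68 ± 0.21), and the mean was 0.40 (camera adjusted p = 7.13e-05, and 0.619 with an estimated correlation), or 0.26 without wild-type 3. Cajal-Retzius genes split, with 8 higher, Ndnf among them (1.03 ± 0.15), and 3 lower, Trp73 (−2.20 ± 0.37) and Reln (−0.82 ± 0.18) among them, adjusted over the list alone. Their mean was 0.066 (camera adjusted p = 0.0174, and 0.619 with an estimated correlation), and the call ended without Arl13b-null 3 (mean 0.012, adjusted p = 0.0644), while the mean was 0.12 without Arl13b-null 1.

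Genes of hypoxia and glycolysis were mostly higher in Arl13b-null 1 and 3. Adm, a vasodilator peptide gene induced by hypoxia, rose by 1.66 ± 0.17 (SE; limma adjusted p = 0.0483), and Aldoc, the brain isoform of aldolase, fell by 2.98 ± 0.19 (adjusted p = 0.0132). Centring ended the Adm call (limma adjusted p = 0.0574). Adjusted over the list alone, 22 of 29 members were higher and 1, Aldoc, was lower. Ldha (1.13 ± 0.17), Vegfa (0.88 ± 0.14), Aldoa (0.83 ± 0.14) and Tpi1 (0.76 ± 0.14) were not past the threshold over all genes. The list mean was 0.38 (camera adjusted p = 1.28e-08, and 0.619 with an estimated correlation), or 0.22 without Arl13b-null 3. Ldha had a mean of 11724 normalized counts in wild-type 2 and 3, 21366 in Arl13b-null 1 and 30937 in Arl13b-null 3.

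Surface ectoderm markers were lower in the same 2 libraries, and camera called the mesenchyme list lower and the red blood cell list higher. Of 19 surface ectoderm genes, 15 were lower adjusted over the list alone and 0 over all genes, with a mean of −1.44 (camera adjusted p = 4.89e-12, and 0.619 with an estimated correlation). Krt5 had a mean of 702 normalized counts in wild-type 2 and 3, 179 in Arl13b-null 1 and 2.46 in Arl13b-null 3, and Krt8 (−2.49 ± 0.61, SE), Krt19 (−1.81 ± 0.34), Sfn (−2.05 ± 0.36) and Perp (−1.93 ± 0.34) were also lower without passing over all genes. The mesenchyme list, with Col1a1 (−1.35 ± 0.47), had a mean of −0.34 (camera adjusted p = 0.000460, and 0.710 with an estimated correlation), with 1 of 34 genes lower adjusted over the list alone and 0 over all genes. Relative to the mean of wild-type 2 and 3, the mesenchyme mean was −0.29 in wild-type 3, −0.31 in Arl13b-null 1 and −0.36 in Arl13b-null 3. Its call ended without wild-type 2 (mean −0.047, adjusted p = 0.293), and the mean was −0.63 without wild-type 3. All 21 red blood cell genes were above 0, with a mean of 1.03 (camera adjusted p = 3.82e-08, and 0.648 with an estimated correlation) and 0 past the threshold, over all genes or adjusted over the list alone. The mean was 1.62 without Arl13b-null 1 and 0.44 without Arl13b-null 3. Hbb-y differed by 1.38 ± 0.44, or by 0.69 without Arl13b-null 3. Without wild-type 2, Krt8 differed by −1.56 and Col1a1 by −0.61; without wild-type 3, Col1a1 differed by −2.09. The endothelial (mean 0.17) and macrophage (0.16) lists were also called by camera (adjusted p = 0.00206 and 0.0105, and 0.648 and 0.713 with an estimated correlation), and both calls ended without Arl13b-null 3 (means 0.071 and 0.10, adjusted p = 0.158 and 0.195), the macrophage call also without wild-type 3 (mean 0.085, adjusted p = 0.281). Without Arl13b-null 1 the endothelial mean was 0.27.

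Lists for cilia, PI3K signalling and axon guidance showed small differences in the 4 coherent libraries. The 64 genes of ciliary structure and trafficking had a mean of 0.027 (camera adjusted p = 0.416), and 40 genes of PI3K-AKT and IGF signalling a mean of 0.012 (adjusted p = 0.696). Of 76 axon guidance genes, 4 were higher and 8 lower adjusted over the list alone. Plxna4, a semaphorin receptor, fell by 0.81 ± 0.075 (SE; limma adjusted p = 0.0374), and the semaphorin gene Sema3c fell by 0.78 ± 0.081 (adjusted p = 0.0478). Centring and inverted counts each ended the Sema3c call (limma adjusted p = 0.0555 and 0.0542). The list mean was −0.048 (camera adjusted p = 0.0403, and 0.648 with an estimated correlation), and the call ended without wild-type 2 or Arl13b-null 1 (means −0.039 and −0.019, adjusted p = 0.174 and 0.686), while the mean was −0.078 without Arl13b-null 3. Lists of axon growth (mean 0.11), postmitotic neurons (0.13) and the cell cycle (0.091) were higher by camera (adjusted p = 0.000767, 0.00105 and 0.00105, and 0.537, 0.537 and 0.713 with an estimated correlation), each with 0 genes past the threshold. By fry their adjusted p was 0.0537, 0.0499 and 0.383, so the neuron list passed there as the hem list did. Quantile normalization ended all 3 calls (adjusted p = 0.883, 0.0855 and 0.0821), and the cell cycle call also ended without wild-type 2 or Arl13b-null 3 (means 0.052 and 0.053, adjusted p = 0.156 and 0.0919).

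The remaining genes past the threshold in the 4 coherent libraries include developmental transcription factors and secreted proteins. Nfix fell by 1.40 ± 0.092 (SE), and Nfib, named after its value was seen, by 1.11 ± 0.11; both belong to the nuclear factor I family of forebrain transcription factors. Tnc, an extracellular matrix glycoprotein of neural stem cells, fell by 1.40 ± 0.14, the protease gene Adamts18 by 1.57 ± 0.13, Upk1b by 1.72 ± 0.15, Ccno by 1.49 ± 0.14 and Etl4 by 1.37 ± 0.071. Spp1, which encodes the secreted protein osteopontin, rose by 1.92 ± 0.19, Pitx1, a homeobox transcription factor, by 1.22 ± 0.10, and the endothelin receptor gene Ednrb by 0.53 ± 0.049. Eif2s3x, on the X chromosome, rose by 0.58 ± 0.047. The limma adjusted p of these genes lay between 0.00631 for Etl4 and 0.0450 for Tnc. Centring ended the calls of Tnc and Spp1 (limma adjusted p = 0.0555 for each). Inverted counts ended those of Ccno and Upk1b (adjusted p = 0.0659 and 0.0776).

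Camera called the lists of Wnt targets and of midbrain, hindbrain and spinal cord in the 4 coherent libraries. Canonical Wnt targets had a mean of −0.097 (camera adjusted p = 0.0240, and 0.619 with an estimated correlation) and the midbrain list a mean of 0.77 over 7 genes (adjusted p = 0.0221, and 0.713). The Wnt call ended without wild-type 2 or Arl13b-null 1 (means −0.071 and −0.037, adjusted p = 0.149 and 0.686), and the midbrain call without wild-type 3 or Arl13b-null 3 (means 0.20 and 0.56, adjusted p = 0.342 and 0.184). The Wnt mean was −0.16 without Arl13b-null 3 and the midbrain mean 1.34 without wild-type 2. Radial glia, Notch, FGF, neural crest, muscle and cartilage, p53 and immediate early gene lists did not pass by camera, with adjusted p of 0.829, 0.364, 0.188, 0.968, 0.421, 0.542 and 0.696. Without wild-type 2, camera called the neural crest and the muscle and cartilage lists higher (means 0.24 and 0.22, adjusted p = 0.0165 and 0.0175, and 0.721 for each with an estimated correlation). The sex-linked list had a mean of −1.41 (camera adjusted p = 7.13e-05, and 0.619 with an estimated correlation).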

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

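The alternatives with 4 libraries and the gene by gene library weights were chosen after the data were seen; the other alternatives to the 6-library fit were planned. The 6-library limma count of 0 genes stayed 0 without a filter, with a stricter filter, centred, quantile normalized, without trend, with robust moderation, with the replicate block and on inverted counts. It was 214 with library weights, whose estimate did not converge, 110 with weights estimated gene by gene, 36 in the 4 coherent libraries and 0 to 4 when 1 library was left out. The weights put Arl13b at 0.020. Whether replicate numbers pair the libraries could not be told. The deviations of same-numbered libraries from their group means correlated at −0.71, −0.71 and 0.62 across genes. Wild-type 1 and Arl13b-null 2, which correlated at 0.71 with each other, pull these group means, so the signs follow from which replicate stood apart. The replicate block gave 0 genes, 111 unadjusted, and 21 lists. Lists past the threshold numbered 0 with an estimated correlation, 0 with fry and 0 with its mixed test, and 9 to 20 when 1 library was left out. The cause was not tested for any of these, except that the 4 libraries leave out the 2 that stood apart.

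Shh turned to 0.016 when centred and 0.26 after quantile normalization. With weights, weights gene by gene and the 4 coherent libraries, Ptch1 was 0.50, 0.36 and 0.39, Shh 0.39, 0.19 and 0.23, Gli2 0.18, 0.14 and 0.16, Pax6 0.12, 0.14 and 0.12, and Hbb-y 2.06, 1.28 and 1.38. In the 4 libraries list means turned to 0.066 (Cajal-Retzius), 0.091 (cell cycle), 0.050 (Notch), 0.40 (diencephalon), 0.77 (midbrain), 1.03 (red blood cells), 0.17 (endothelium), 0.16 (macrophages) and 0.11 (muscle). They also turned to 0.042 (neural crest), 0.012 (PI3K-AKT and IGF), 0.14 (FGF) and 0.027 (cilia). For the ventral telencephalon camera's direction turned, while the mean stayed below 0 at −0.083. When 1 library was left out, values ranged from −0.046 to 0.18 for Inpp5e, −0.64 to 0.86 for Shh, −2.58 to 3.50 for Hbb-y, −1.14 to 0.20 for Gli1, −1.12 to 0.62 for Ptch1, −1.56 to 0.51 for Smo, −1.94 to 0.70 for Gli2, −2.27 to 0.61 for Gli3, −1.37 to 0.47 for Pax6 and −1.45 to 0.33 for Gsx2. List means ranged from −0.22 to −0.022 for axon guidance, −1.05 to 0.17 for Hedgehog targets, −1.63 to 0.14 for Cajal-Retzius, −0.17 to 0.64 for axon growth, −1.62 to 0.076 for radial glia, −1.58 to 0.75 for cell cycle, −0.97 to 0.36 for Notch, −1.36 to 0.59 for diencephalon, −0.94 to 0.87 for midbrain, −1.24 to 1.13 for red blood cells, −1.10 to 0.032 for endothelium, −0.82 to 0.010 for macrophages, −0.96 to 0.047 for neural crest and −0.74 to −0.020 for muscle.

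In the 4 coherent libraries, the 36 genes became 66 after quantile normalization, 7 without trend, 98 with robust moderation and 6 to 725 when 1 library was left out. Lists numbered 0 with an estimated correlation, 3 with fry and 12 with its mixed test. Leaving out 1 library moved Pax6 from −0.089 to 0.33 and neural crest from −0.15 to 0.24. Depth limits genes of a few reads, where 1 read is worth between 0.537 and 1.31 normalized counts.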

Other observations

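The tests below were chosen after the results were seen. Wild-type 1 held more transcripts of cornified skin and of maturing neurons than the 4 coherent libraries. A list of 14 genes of cornified epidermis, put together after these libraries were inspected, lay 4.78 above wild-type 2 and 3 on the log2 scale there, with Krt10 at 26210, Krt1 at 14540 and Lor at 11705 normalized counts. In Arl13b-null 2 this list lay 0.70 above, with Lor at 2045, Krt1 at 995 and Krt10 at 295 normalized counts. There 4 of the 14 genes exceeded 100 normalized counts, while Hrnr and Krtdap had 0. A list of 15 genes of maturing excitatory neurons lay 2.56 above in wild-type 1 and 4.94 above in Arl13b-null 2, where Nrgn had 67446 normalized counts. Adult beta globins (Hbb-bs and Hbb-bt together) had 49.2 times the counts of the embryonic Hbb-y in wild-type 1, and between 0.0320 and 0.0351 times in the 4 coherent libraries. In Arl13b-null 2 the adult globin list was low instead, at −3.64 from wild-type 2 and 3, against 2.53 in wild-type 1. The endothelial, macrophage and mesenchyme lists differed by −1.89, −1.42 and −3.74 in Arl13b-null 2, and by 0.46, 0.42 and −0.65 in wild-type 1. Xist had 15101 normalized counts in wild-type 1 and 244 in Arl13b-null 2, and Ddx3y had 0.537 and 0. Wild-type 1 thus differs from wild-type 2 and 3 in sex-linked transcripts, and sex does not follow genotype over all 6 libraries.

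Wild-type 1 and Arl13b-null 2 stood apart from the other 4 libraries. The tables argue against sequencing depth, because 6653 abundant genes differed from the coherent libraries by a median of 0.941 in Arl13b-null 2 and 0.464 in wild-type 1, against at most 0.0727 among the coherent libraries. They argue against genotype as the whole source, because wild-type 1 carries the other label. More differentiated material than in the other libraries may be part of both. In each, 36 of 36 cell cycle genes were lower by over 1, and the neuron list was higher by 0.729 and 0.990. Both lists had been seen to differ before this test was chosen, so the values describe these libraries and do not test this source. For epidermal tissue in wild-type 1 the cutoff did not decide, as 13 of 14 genes exceeded 100 normalized counts but 1 or 2 also did in each coherent library. The 14 genes held 0.249% of the normalized counts in wild-type 1, 0.00970% in Arl13b-null 2 and at most 0.00164% in a coherent library. Their list was put together after these libraries were inspected, so the excess describes wild-type 1 and does not test its source. Wild-type 1 and Arl13b-null 2 differed in opposite directions in adult globins, endothelium and macrophages, so they may not share 1 source. Later age, other tissue and a wrong label cannot be told apart from these tables.

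The genes past the threshold in the 4 coherent libraries, Gas1, Cdon and Fgf15 among them, were weighed against 2 sources other than genotype. Sex cannot be told apart from genotype, as both divide these libraries in the same way. Of the 36 genes, 30 are outside the sex-linked list, but that list holds only 6 genes. The 30 include Eif2s3x, on the X chromosome, and others may also differ by sex. A smaller share of cortical tissue stays open, because with 2 libraries per group a gene passes where Arl13b-null 1 and 3 lie close: the median difference of −0.13 between these 2 libraries over the 22 genes that fell outside the sex-linked list follows from that choice and decides nothing.

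For the 6-library counts, 3 against 3 make 10 splits, too few for a share under 0.05. The real split gave 0 genes in limma, with 163 at an unadjusted p under 0.05, and the highest other count was 0; as every split reaches 0, this says nothing. For lists, the real split gave 20 and the other splits between 12 and 21.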
